A study of Mus musculus with 2 samples.

How the data were processed

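Total RNA was measured by sequencing in the left cerebral cortex of 2 male B6CASTF1/J mice aged 10 days, the hybrid offspring of C57BL/6J and CAST/EiJ parents. Per the labels, the tissue came from The Jackson Laboratory, each library was made from 300 ng of RNA, and a mix of ERCC spike-ins (synthetic RNAs of known relative amount) was added. The labels number the libraries as biological replicates and number the animals separately, but give both the same donor identifier. They were read as 2 animals of 1 group. No second group, treatment or control sample belongs to the design, so no test between groups was made and no p-value is given.

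The values used were deposited by the authors as 3 tables per library, built on the mouse genome mm10 with GENCODE annotation M21, per the deposited descriptions of the files. The first quantification, made from alignments to the transcriptome, gives a gene table and a transcript table. Per the file headers it holds expected counts, TPM (length-normalised abundance scaled to the same sum in each library, over all records, spike-ins and mitochondrial genes included), FPKM and the percent of each gene's abundance held by each transcript. Its gene table also holds posterior mean estimates with interval bounds, and the level of these intervals is not given in the sources used here. The second quantification was made from the reads with an index, and per the file headers it holds estimated counts and TPM per transcript, which were summed by gene. The column layouts are those that the programs RSEM and kallisto write, but the programs, their versions and the strand setting are not given in the sources used here. Values of antisense genes such as Kcnq1ot1, Airn and Tsix depend on that unstated strand setting. The reference is the genome of 1 parent strain, and alleles were not separated.

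In the first quantification the deposited effective length of a transcript was its length minus 99 bases, and 0 for transcripts of 99 bases or fewer. This raises the TPM of short RNAs. All 55536 annotated genes matched the annotation by versioned identifier. The gene tables also held 96 ERCC records, 1 record of the phage phiX and 26248 short numbered records without a name. Depth was 31254528 expected counts in replicate 1 and 30218308 in replicate 2. At an effective length of 1 kb, 1 TPM equalled 20.5 counts in replicate 1 and 19.7 counts in replicate 2.

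Levels are TPM of the first quantification, given per library or as the mean and SD over the 2 libraries. A gene was called detected at 1 TPM or more in both libraries. Lists of genes were taken from textbook knowledge for 18 cell types, regions and states: glutamatergic neurons, upper-layer and deep-layer projection neurons, GABAergic interneurons, astrocytes, oligodendrocyte precursors, committed and myelinating oligodendrocytes, microglia, endothelial cells, mural cells and fibroblasts, choroid plexus and ependyma, erythroid cells, immature neurons and progenitors, and striatal, thalamic, hippocampal and cerebellar neurons. Lists for the cell cycle, immediate early genes, ionotropic glutamate receptors, GABA-A receptor subunits, imprinted genes, sex-linked genes, ribosomal RNA loci and long non-coding RNAs were added, giving 26 lists with 269 members, of which 267 matched a gene. Rn18s-rs5 and Rn45s had no match. Also fixed were 10 pairs of an earlier and a later expressed gene and 22 genes with known isoforms. These lists, the tests and the other settings named further on, where not said otherwise, were chosen before the data were examined. A further 6 lists were fixed after part of the data had been seen.

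The ratio of the libraries was log2 of replicate 2 over replicate 1 with 0.1 added to each TPM, for genes with a mean expected count of 100 or more. The Pearson and Spearman correlations were taken across protein-coding genes with a mean of 1 TPM or more, on log2 of TPM plus 1. A common biological coefficient of variation was estimated with estimateDisp of edgeR 4.0.16 from rounded expected counts, with an intercept, TMM factors and a mean expected count of 10 or more. A chi-square statistic over the same minimum count asked whether both libraries could be 1 library deposited again. The shift of a list between the libraries was the median log2 ratio of its members with a mean expected count of 20 or more, for lists with at least 3 such members. The tests on choroid plexus and motile cilia genes used a mean expected count of 5 or more. It was placed as a percentile among 10000 random lists of equal size, matched on mean expression in 20 bins. A list is called outside the random lists when it lies beyond their central 95%. Ratios of CPM (expected counts scaled to the same total in each library) carry 95% Clopper-Pearson intervals on the counts of both libraries. These intervals cover counting error alone, and reads without molecular identifiers are not independent molecules. Where records outside the comparisons were checked for signal, a count of 0 was taken to allow 3 counts per library. A count was called whole when its deposited value, printed to 2 decimals, ended in zeros, with no further tolerance.

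The genes named are the 10 nuclear protein-coding genes with the highest mean TPM, the 3 highest members of each list, every sex-linked member, the 6 genes with the highest and the 6 with the lowest ratio between the libraries, every gene pair, and the top transcript of each isoform gene with 5 TPM or more. Some genes and transcripts under this rule are not reported here. Other genes, among them Scn4b, mt-Co3, Gm28437, Rn7sk, Drd1, Adora2a, Fos, Clic6 and members of the 6 later lists, were chosen after their values were seen. The most abundant transcript was compared between the quantifications for protein-coding genes with 2 or more annotated transcripts and a mean of 5 TPM or more.

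Alternatives were other floors, pseudocounts and count minimums, FPKM, posterior means, scaling by TMM, by size factors of DESeq2 1.42.0, by CPM or by the spike-in total, TPM rescaled to nuclear protein-coding genes, the second quantification, and leaving out each replicate. The method was tested on simulated data for replicate 2 against replicate 1 with 28825 genes. It called 99% of the genes raised 3-fold, 100% of the genes lowered 4-fold and 1 unchanged gene. The simulation drew counts per gene and called ratios of CPM, without shared reads or estimated transcript lengths. Its rate of false calls therefore does not carry over to the ratios of TPM used for the real libraries. A coefficient of variation of 0.1 came back as 0.101 with no gene changed and as 0.141 where genes had been changed, so changed genes raise this estimate. The work used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Alignments and signal tracks were not analysed here.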

Results

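RNA of the left cerebral cortex was sequenced from 2 male mice aged 10 days, both of the hybrid B6CASTF1/J. They formed 1 group, with 1 library per animal, and the libraries are called replicate 1 and replicate 2. Replicate 1 held 31254528 expected counts and replicate 2 held 30218308. Values are TPM, and errors are the SD of the 2 libraries (n = 2), which reflects the spread of these samples alone. Positions refer to the mouse genome mm10.

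The first question was which genes the cortex expressed most at this age. The most abundant nuclear protein-coding gene was Tuba1a (ENSMUSG00000072235.6, chromosome 15, 98949837 to 98953703), an alpha-tubulin of growing neurons, at 2059.6 ± 27.4 TPM (SD, n = 2). It was followed by the translation factor Eef1a1 (ENSMUSG00000037742.14, chromosome 9, 78478449 to 78489151) at 1797 ± 34.7 and by the actin gene Actb (ENSMUSG00000029580.14, chromosome 5, 142903115 to 142906754) at 1671 ± 17.6. Cytoskeletal genes also included Tubb2a at 1316 ± 17.9 and Actg1 at 1113 ± 8.06. The ribosomal protein gene Rpl41 reached 1172.5 ± 20.9, the calmodulin gene Calm2 1101 ± 46.0 and the cyclophilin gene Ppia 1054 ± 63.1. The chaperone gene Hspa8 stood at 1038 ± 54.8. Of 22028 annotated protein-coding genes, 13124 (59.6%) were detected in both libraries, as were 293 of 5854 lincRNA genes.

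Nuclear protein-coding genes took 82.5 ± 0.41% of the expected counts (n = 2). The mitochondrial genome took 6.34% in replicate 1 and 5.52% in replicate 2, and most of this was mitochondrial ribosomal RNA, at 4.57 ± 0.43% of all counts. This share leaves out reads placed on nuclear copies of mitochondrial genes. Gm28437, a near-identical copy of mt-Co3, alone held 48765 counts in replicate 1 and 57504 in replicate 2. The 7SL RNA genes Rn7s1 (ENSMUSG00000099021.1, chromosome 12, 69159295 to 69159594) and Rn7s2 (ENSMUSG00000099250.1, chromosome 12, 69361182 to 69361481), the RNA of the signal recognition particle, took 3.60 ± 0.0031% of the counts. Because they are short, they took 27.4 ± 0.17% of the TPM, which left 48.5 ± 0.70% for nuclear protein-coding genes. The second quantification gave these short RNAs almost nothing and nuclear protein-coding genes 78.6 ± 0.96% of the TPM, so absolute TPM differed between the quantifications. Rn7sk, which controls transcript elongation, took 4.26 ± 0.043% of the TPM. ERCC spike-ins took 0.357 ± 0.0036% of the counts. Across 41 spike-in species the median log2 ratio of replicate 2 to replicate 1 in CPM was -0.01, with an SD of 0.22.

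The next question was which cell types and regions the tissue contained. Across the 18 lists for cell types, regions and immature cells, 145 of 168 members were detected in both libraries. Glutamatergic neurons had 8 of 8 members detected and a list median of 84.7 ± 1.02 TPM (n = 2), the highest of these 18 lists in the first quantification, while in the second the erythroid median of 137 exceeded theirs of 123. Their top members were the synaptic gene Nrgn at 862 ± 32.2, the vesicular glutamate transporter gene Slc17a7 (ENSMUSG00000070570.5, chromosome 7, 45163949 to 45176142) at 491 ± 10.8 and the kinase gene Camk2a at 485 ± 2.13. Upper-layer projection neurons had 8 of 8 members detected and a median of 45.2 ± 2.16, led by Plxnd1 at 87.3 ± 4.69, Cux2 at 85.0 ± 1.24 and Cux1 at 61.3 ± 1.22. Deep-layer projection neurons had 10 of 10 detected and a median of 20.03 ± 0.785, led by Crym at 73.3 ± 0.608, Tbr1 at 45.3 ± 1.61 and Bcl11b at 34.7 ± 0.403. GABAergic interneurons had 15 of 15 detected and a median of 13.6 ± 0.672. In that list the neuropeptide gene Sst (ENSMUSG00000004366.4, chromosome 16, 23889573 to 23890958) reached 175 ± 0.29, the GABA-synthesis gene Gad1 80.7 ± 5.2 and Reln 69.6 ± 3.01.

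Glial lists were also detected almost in full. Astrocytes had 12 of 12 members detected and a median of 58.9 ± 4.88 TPM (n = 2), with the glutamate transporter gene Slc1a2 (ENSMUSG00000005089.15, chromosome 2, 102658659 to 102790784) at 625 ± 0.891, Glul at 521 ± 12.3 and Aldoc at 158 ± 9.42. Oligodendrocyte precursors had 8 of 8 detected and a median of 14.5 ± 0.361, with Olig1 at 50.2 ± 1.89, Pdgfra at 35.2 ± 1.68 and Vcan at 17.6 ± 0.509. Committed oligodendrocytes had 6 of 6 detected and a median of 7.24 ± 0.435, with Gpr17 at 32.9 ± 0.778, Bcas1 at 20.5 ± 0.382 and Itpr2 at 8.86 ± 0.177. Myelinating oligodendrocytes had 10 of 12 detected and a median of 13.9 ± 1.22. The myelin genes Mbp (ENSMUSG00000041607.17, chromosome 18, 82475146 to 82585637) and Cnp stood at 154 ± 10.0 and 46.6 ± 2.52, while the late markers Opalin and Ermn stayed at 0.26 ± 0.085 and 0.605 ± 0.078. Microglia had 13 of 13 detected and a median of 13.98 ± 1.29, with Csf1r at 28.9 ± 1.25 and P2ry12 at 25.9 ± 1.66.

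Vessels were represented by endothelial cells, with 10 of 10 members detected and a median of 11.2 ± 0.290 TPM (n = 2). The tight-junction gene Cldn5 stood at 37.1 ± 0.651, the glucose transporter gene Slc2a1 at 31.6 ± 1.99 and Itm2a at 25.2 ± 0.919. Mural cells and fibroblasts had 12 of 12 detected and a median of 12.4 ± 0.803, with Igf2 at 116 ± 21.5, Rgs5 at 44.3 ± 1.61 and Vtn at 38.5 ± 4.79. Erythroid cells had 5 of 7 detected, and their median depended on the library, at 55.0 in replicate 1 and 34.4 in replicate 2. The globin genes Hbb-bs, Hba-a1 and Hba-a2 averaged 355 ± 107, 322 ± 66.1 and 298 ± 76.8. The choroid plexus and ependyma list had 2 of 10 detected, with a median of 0.50 in replicate 1 and 2.02 in replicate 2. Its top members were Ttr at 7.35 and 303.5 in replicates 1 and 2, Foxj1 at 2.00 ± 0.240, and Folr1 at 0.42 and 3.46.

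The cell cycle list had 11 of 12 members detected and a median of 2.5025 ± 0.039 TPM (n = 2), with Pcna at 27.7 ± 1.12, Top2a at 4.94 ± 0.940 and Rrm2 at 4.58 ± 0.693. The list for immature neurons and progenitors had 10 of 12 detected and a median of 9.21 ± 1.63. In it the neuronal cytoskeleton genes Stmn2, Tubb3 and Dcx reached 909.99 ± 10.7, 618 ± 24.6 and 81.3 ± 0.658, while the progenitor genes Eomes and Neurog2 stayed at 0.185 ± 0.106 and 0.06 ± 0.014.

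Lists for neighbouring brain regions gave a background against which the cortical lists were set. Striatal neurons had 8 of 8 members detected and a median of 13.9 TPM in replicate 1 and 9.08 in replicate 2, with Ppp1r1b at 48.8 ± 14.0 and Rgs9 at 17.1 ± 3.37 (n = 2). Thalamic neurons had 3 of 6 detected and a median of 2.03 ± 0.216, with Ramp3 at 17.5 ± 2.07, Prkcd at 9.10 ± 0.099 and Lef1 at 3.08 ± 0.325. Hippocampal neurons had 4 of 6 detected and a median of 1.68 in replicate 1 and 2.64 in replicate 2, with Fibcd1 at 6.31 ± 0.134, Prox1 at 4.30 ± 0.580 and Trhr at 2.86 ± 1.03. Cerebellar neurons had 1 of 5 detected and a median of 0.15 ± 0.028, with Car8 at 6.84 ± 0.297, Fat2 at 0.21 ± 0.085 and Cbln3 at 0.15 ± 0.028. Cortical neurons also express some members of these lists, so the levels are not shares of tissue.

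**Figure D1:**
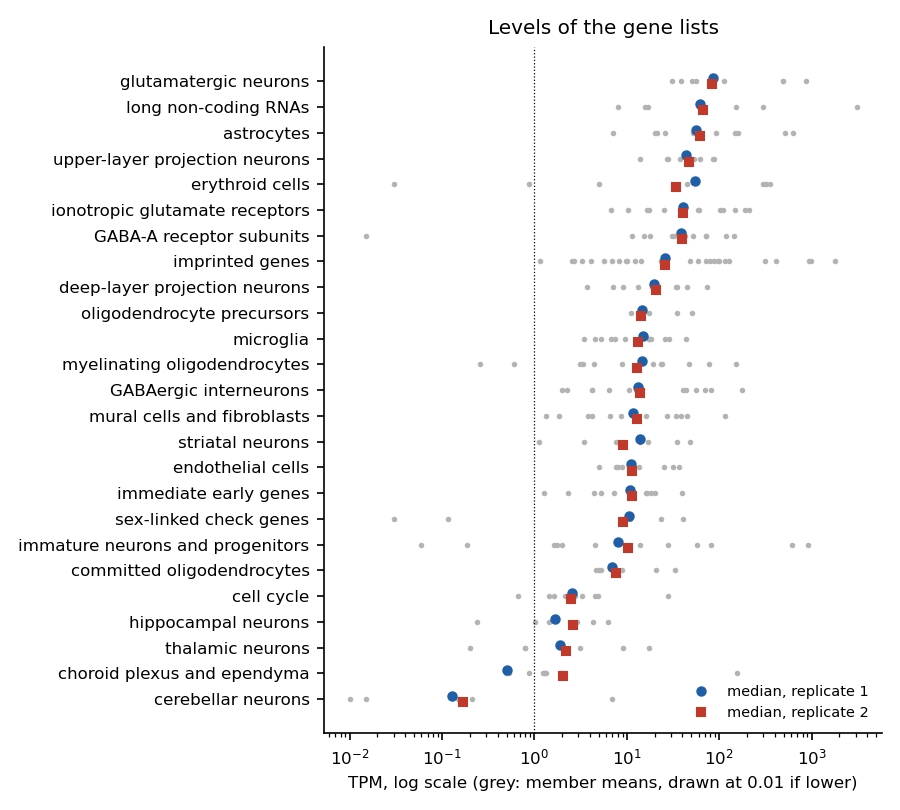
Levels of the gene lists in TPM on a log axis. Grey points are members (mean of 2 libraries, drawn at 0.01 where lower), coloured points are the list medians of replicates 1 and 2, and the dotted line marks 1 TPM; the ribosomal RNA list is left out, and the cerebellar list has the lowest median at 0.15.

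All 15 ionotropic glutamate receptor genes were detected, with a median of 40.3 ± 0.078 TPM (n = 2), and Gria2, Grin1 and Grin2b led at 209 ± 0.247, 188 ± 1.73 and 149 ± 0.467. Of 13 GABA-A receptor subunit genes, 12 were detected, with a median of 39.1 ± 0.502. The subunit Gabra6, typical of cerebellar granule cells, stood at 0.015 ± 0.021. Immediate early genes, which neuronal activity induces, had 12 of 12 detected and a median of 11.1 ± 0.428, with Egr1 at 39.9 ± 3.86, Jun at 20.4 ± 2.67 and Nr4a1 at 18.4 ± 1.74.

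Imprinted genes, which are expressed mainly or only from 1 parental allele in at least some tissues, had 29 of 30 members detected. Their median was 26.0 ± 0.166 TPM (n = 2), and alleles were not separated. The maternally expressed RNA Meg3 (ENSMUSG00000021268.17, chromosome 12, 109541001 to 109571726) reached 1775 ± 105, Rian 985 ± 14.9 and Gnas 927 ± 23.7. Among long non-coding RNAs 8 of 8 were detected, with a median of 64.2 ± 2.96, led by Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) at 3068 ± 97.0, Snhg11 at 295 ± 13.3 and Miat at 151 ± 11.1. Of the ribosomal RNA loci, Gm26917 stood at 14837 ± 566, Gm42418 at 2608 ± 26.8 and AY036118 at 0. With 3 matched loci and 2 detected, the median of that list was 2608 ± 26.8.

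The sex-linked genes checked the labels, which name both animals as male. The Y-linked genes Eif2s3y (ENSMUSG00000069049.11, chromosome Y, 1010543 to 1028847), Ddx3y, Uty and Kdm5d stood at 40.1 ± 1.36, 23.5 ± 0.276, 10.9 ± 0.799 and 8.78 ± 1.24 TPM (n = 2). Xist (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), the RNA that silences an X chromosome in females, had 5 and 7 counts and 0.03 ± 0.028 TPM, and its antisense Tsix 0.115 ± 0.092. With 4 of 6 members detected, the list median was 9.84 ± 1.02.

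The third question was where the cortex stood in development, read from 10 pairs of an earlier and a later expressed gene. In 7 pairs the later gene was higher in both libraries. The chloride exporter gene Slc12a5 (ENSMUSG00000017740.17, chromosome 2, 164960802 to 164999731), which makes GABA inhibitory, stood at 165 ± 1.20 TPM against 13.1 ± 0.431 for the importer gene Slc12a2, 12.5 ± 0.503 times as high (n = 2). The vesicular transporter gene Slc17a7 exceeded Slc17a6 22.6 ± 1.59 times, and the scaffold gene Dlg4 exceeded Dlg3 6.22 ± 0.188 times. A smaller difference separated Map1b from Map2, at a ratio of 0.887 ± 0.0022.

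In 3 pairs the earlier gene was higher. Grin2b (ENSMUSG00000030209.14, chromosome 6, 135713233 to 136173511), the juvenile NMDA receptor subunit, exceeded Grin2a (ENSMUSG00000059003.12, chromosome 16, 9567898 to 9995560) by a ratio of 2.49 ± 0.043 (n = 2). Sst exceeded Pvalb (ENSMUSG00000005716.16, chromosome 15, 78191114 to 78206400), the marker of late-maturing fast-spiking interneurons, by 78.4 ± 4.58, with Pvalb at 2.24 ± 0.134 TPM. The sodium channel gene Scn3a exceeded Scn1a by 1.17 ± 0.031. Each of these ratios, and of those above with the later gene higher, differed from 1 by more than the SD of the 2 libraries, but no second age was measured.

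**Figure D2:**
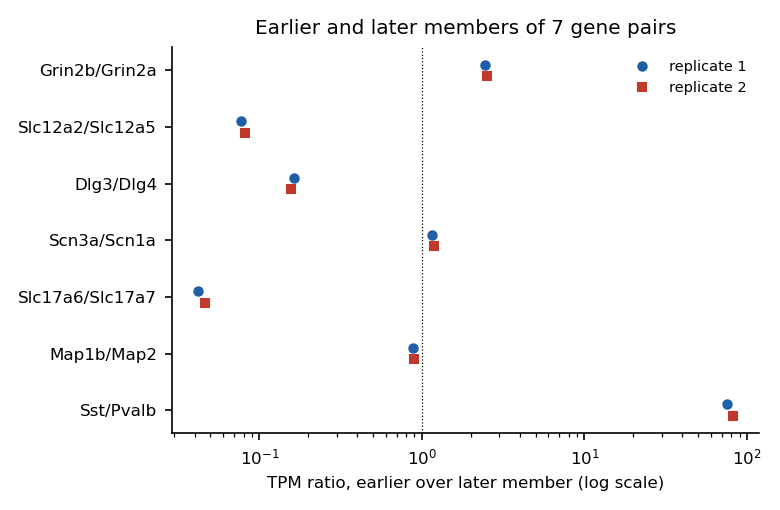
Ratio of the earlier to the later gene of 7 of the 10 pairs, on a log axis, with 1 point per replicate. The ratios ran from 0.0444 for Slc17a6 over Slc17a7 to 78.4 for Sst over Pvalb, as means of 2 libraries.

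The fourth question was which isoforms of 22 neural genes predominated. The main transcript of Mapt was Mapt-204 (ENSMUST00000106992.9, chromosome 11, 104231390 to 104332090), a transcript of 10 exons coding for 372 amino acids, at 87.8 ± 1.91% of the TPM of the gene (SD, n = 2) and 77.5 ± 3.51% in the second quantification. App-201 (ENSMUST00000005406.11, chromosome 16, 84954443 to 85173758), coding for 695 amino acids, held 93.0 ± 0.303%. Snap25-201 (ENSMUST00000028727.10, chromosome 2, 136713453 to 136782428) held 64.5 ± 1.66%. Among AMPA receptor genes, Gria1-201 held 77.9 ± 3.39%, Gria2-202 55.5 ± 0.593%, Gria3-201 70.0 ± 2.17% and the 433-residue Gria4-203 49.8 ± 0.869%.

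Other top transcripts were Grin1-201 at 43.9 ± 4.55%, Cdc42-201 at 60.4 ± 0.160%, Ank3-244 at 22.7 ± 0.990%, Nfasc-202 at 55.4 ± 2.66%, Ncam1-204 at 41.7 ± 1.90% and Clta-205 at 64.8 ± 0.159%. Map2-204 held 41.5 ± 0.368%, Bin1-201 61.7 ± 2.00% and Camk2d-206 25.8 ± 7.28% (n = 2). On means of the 2 libraries the second quantification named the same top transcript for 19 of the 22 genes. For Mbp the first named Mbp-211 (ENSMUST00000133193.8, chromosome 18, 82554516 to 82585627) at 51.4 ± 4.25%, and the second named Mbp-201 at 28.7 ± 0.096%. For Dlg4 they named Dlg4-203 at 52.9 ± 0.302% and the 130-residue Dlg4-206 at 26.9 ± 0.196%, and for Gphn they named Gphn-202 at 46.0 ± 2.16% and Gphn-201 at 50.5 ± 8.12%. The last 2 differences rested on replicate 1, since the rivals were close, with Dlg4-203 at 25.8 ± 2.27% in the second quantification and Gphn-201 at 44.6 ± 6.01% in the first. In replicate 2 alone both quantifications put Dlg4-203 above Dlg4-206 (27.4% and 26.7% in the second) and Gphn-201 above Gphn-202 (48.8% and 44.4% in the first). Across 9628 protein-coding genes the top transcript was the same in both quantifications for 76.4%. Between the libraries it was the same for 91.2% of the genes in the first quantification and for 87.8% in the second, so the choice of quantification moved more top transcripts than the choice of library.

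The last question was how far the 2 animals differed. The transthyretin gene Ttr (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), the most abundant gene of choroid plexus, had 164 counts in replicate 1 and 6499 in replicate 2, a ratio of 41.0 in CPM (95% interval 35.1 to 48.2) and a log2 TPM ratio of 5.35. Each value is 1 library per animal, so these differences have no replicate check. In the choroid plexus and ependyma list 7 of 7 members with enough counts were higher in replicate 2, with a median log2 ratio of 2.16, among them Clic6 at 0.36 and 2.34 TPM. Striatal genes were lower in replicate 2 in 8 of 8 members, with a median of -0.40, as for the dopamine receptor gene Drd1 at 17.4 and 10.2 TPM and the adenosine receptor gene Adora2a at 10.3 and 5.02. Scn4b (ENSMUSG00000046480.6, chromosome 9, 45138395 to 45154152), a sodium channel subunit abundant in striatum, stood at 5.55 and 2.58 TPM, with a log2 ratio of -1.08.

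Other lists also shifted. Erythroid genes were lower in replicate 2 in 5 of 6 members, with a median log2 ratio of -0.58. Myelinating oligodendrocyte genes were lower in 10 of 11, with a median of -0.24. Genes of immature neurons and progenitors were higher in 9 of 10, with a median of 0.31. Their most abundant members moved little, with -0.02 for Stmn2, 0.08 for Tubb3 and 0.02 for Dcx, against 0.26 for Sox4 and 0.35 for Sox11. Hippocampal genes were higher in 6 of 6, with a median of 0.58. Among these, Fibcd1 had 0.04, Prox1 0.27 and Trhr 0.73. The others had few counts, with 28 and 49 for C1ql2, 22 and 62 for Dsp and 25 and 36 for Iyd. Immediate early genes were higher in 12 of 12, with a median of 0.19, as for Fos at 5.14 and 9.45 TPM. GABA-A receptor genes were lower in 10 of 12, by the small median of -0.05. Astrocyte genes were higher in 9 of 12, with a median of 0.10 that fell to -0.0018 in the second quantification. Of 24 lists with enough counts these 9 lay outside the central 95% of the random lists. Random lists hold unrelated genes, while genes of 1 cell type move together between any samples, so this describes the lists and does not test a difference between the animals. The percentiles were 0 for the striatal, erythroid and myelinating lists, 0.62 for GABA-A receptors, 98.0 for astrocytes, 99.2 for immediate early genes, 99.99 for hippocampal neurons and 100 for the choroid and immature lists. Under all 5 scalings and quantifications 7 of them stayed outside, but not astrocytes or immediate early genes. Scaling the same counts by TMM, DESeq2 size factors or the spike-in total moves all log2 ratios almost equally. The percentiles under these 3 were therefore nearly identical by construction, and they count as 1 setting. Deep-layer projection neuron genes, with a median of -0.03, and long non-coding RNAs, with a median of 0.08, kept their sign under all 5. They lay outside under these 3 scalings of counts, though not in TPM of either quantification. The other lists are not given a direction, since some changed sign with the scaling.

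**Figure D3:**
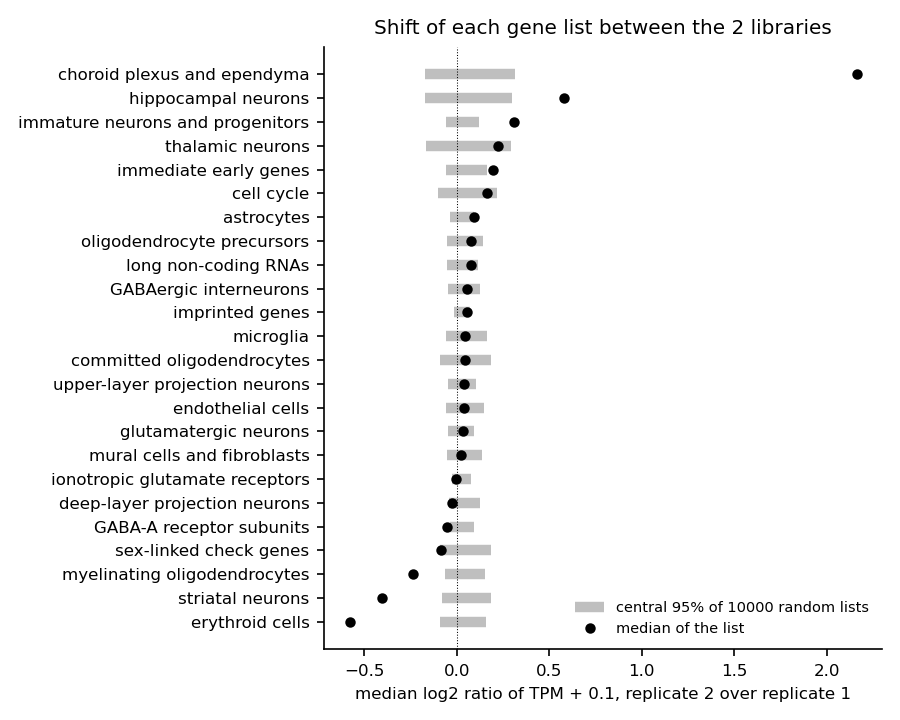
Median log2 ratio of TPM, replicate 2 over replicate 1, of 24 gene lists (points), with the central 95% of 10000 random lists of equal size and matched expression (bars). The choroid plexus list lies highest at 2.16 and the erythroid list lowest at -0.58; the small astrocyte shift of 0.10 changed sign in the second quantification.

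Single genes rarely differed. Among 12835 genes with a mean expected count of 100 or more, the median log2 ratio was 0.04 with an SD of 0.20, and 24 genes (0.187%) were over 2-fold apart, 13 higher in replicate 2 and 11 higher in replicate 1. In the second quantification 58 genes were over 2-fold apart, 15 higher in replicate 2 and 43 higher in replicate 1. Besides Ttr, the genes furthest up in replicate 2 were Tmem72 (ENSMUSG00000048108.13, chromosome 6, 116679063 to 116716913) with a log2 ratio of 3.05, the processed pseudogene Gm6565 with 2.45, Gm20388 with 2.25, Gm45837 with 2.03 and the titin gene Ttn with 1.43. Ttn had 218 and 208 counts, so its TPM ratio did not come from its counts. In the other direction stood 1700047I17Rik2 (ENSMUSG00000094103.2, chromosome 12, 55199592 to 55217168) with 531.84 counts in replicate 1 and 0 in replicate 2. However, its deposited intervals, which go with the posterior means, overlapped, and the second quantification gave it almost 0 in both. 1700047I17Rik2 was followed by the processed pseudogenes Rps12l1 with -5.32 and Gm6361 with -3.47 and by Fam220a with -1.76. Then came Gm45623 (ENSMUSG00000110086.1, chromosome 13, 56752371 to 56753827) with -1.68 and the small nucleolar RNA Rnu3a with -1.27. Of the 24 genes, 18 were protein-coding and 5 were pseudogenes. In both quantifications 4 were over 2-fold apart the same way, which were Ttr, Ttn, Scn4b and Gm45623, and the CPM ratio was also over 2-fold for 3 of these, without Ttn.

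A further split concerned the mitochondrial gene mt-Co3 (ENSMUSG00000064358.1, chromosome M, 8607 to 9390), at 1904 TPM in replicate 1 and 891 in replicate 2. Its near-identical nuclear copy Gm28437 (ENSMUSG00000101111.1, chromosome 1, 24613189 to 24613971) stood at 3474 and 4268, and 99.9% of the 31-base words of mt-Co3 also occurred in it. In CPM the ratio of replicate 2 to replicate 1 was 0.464 for mt-Co3, 1.22 for Gm28437 and 0.952 for their sum, against 0.883 for the other 12 mitochondrial protein-coding genes together. The second quantification did not show the split, with mt-Co3 at 3927 and 3798 TPM and Gm28437 at 4136 and 4135.

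Across 13347 protein-coding genes the libraries correlated with a Pearson r of 0.994 and a Spearman rho of 0.995. This correlation is across genes, which are not independent replicates. The common biological coefficient of variation was 5.31%. The chi-square per degree of freedom was 5.06 over 18515 genes, above the 1 that counting noise alone would give, and the libraries were not copies of each other. For 711 of the 12835 genes (5.54%) the deposited intervals of the libraries did not overlap, and these included 5 of the 24 genes over 2-fold apart. These intervals go with the posterior mean estimates and not with the TPM of the ratios, which can lie outside them. Ttn in replicate 1 had 0.2 TPM and an interval from 0.795 to 2.51.

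**Figure D4:**
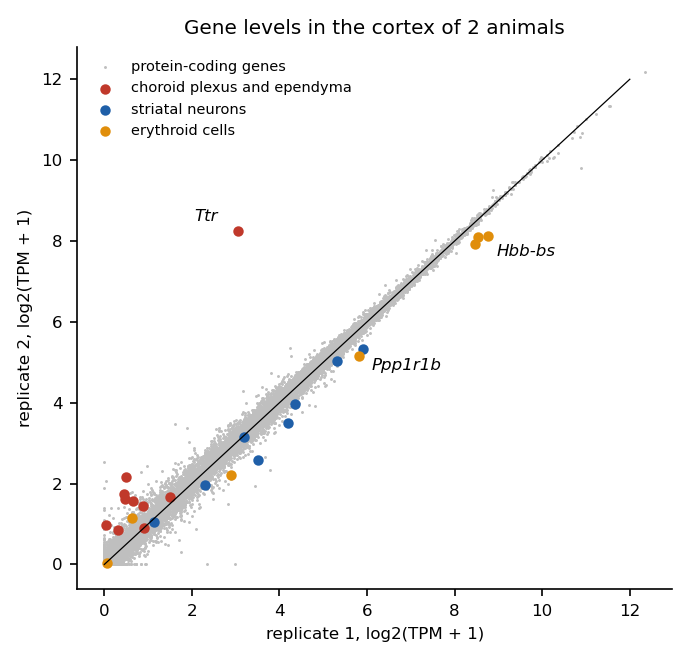
Log2 of TPM plus 1 in replicate 2 against replicate 1 for protein-coding genes with a mean count of 1 or more; each point is a gene, the line marks equality, and the choroid plexus, striatal and erythroid lists are coloured. Ttr lies furthest above the line among the choroid genes, at 7.35 TPM in replicate 1 and 303.5 in replicate 2.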

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

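The test on CPM and every check on whole counts, for the choroid and striatal lists too, were chosen after the result was seen; the other tests were set before theirs. Both animals belong to 1 group, so the tests cover reads, transcript length and tissue or cells from outside the cortex, and no biological difference between the animals was tested.

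The short numbered records without a name drew counts although no comparison uses them. Their total was 4.89 expected counts in replicate 1 and 4 in replicate 2, above the 3 counts that a count of 0 allows. That limit is for a single count of 0, so a sum over so many records can pass it without a signal. Of 26248 records, 3 had a count in each library and 2 had one in both. They are 61 to 259 bases long, and 26185 of them are 99 bases or shorter, which have an effective length of 0 in these files, so almost none has a TPM. What they stand for is not given in the sources used here, and no explanation was tested.

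Choroid plexus genes were higher in replicate 2, with Ttr at 7.35 and 303.5 TPM. Reads shared between gene copies are argued against, since, at a mean expected count of 5 or more as in each test of this pattern, the first list was still higher in the second quantification by a median log2 of 2.01, in 9 of 10 members, and 10 of 10 members had whole counts, with no fraction in the 2 decimals printed. Ependymal cells as the source are also argued against, since 14 genes of motile cilia had a median of 0.14 with an SD of 0.46, 9 up and 5 down. Choroid plexus tissue in the piece of replicate 2 may be a source, but its test stayed between the bounds of 0.5 and 1 set for it. The striatal test below had only to pass -0.2, so the outcomes of both tests do not rank these sources. A second list of 12 choroid genes was higher in 12 of 12 with a median of 0.69, from 0.21 to 2.99, and in 8 of 8 at a mean count of 20 or more, while 4 of the 12 were detected in both libraries.

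Striatal genes were lower in replicate 2, with Ppp1r1b at 58.7 and 38.9 TPM. Shared reads are argued against here too, by a median log2 ratio of -0.47 for the first list in the second quantification, in 7 of 8 members, with 8 of 8 members at whole counts. Striatal tissue in the piece of replicate 1 is a candidate source that may explain this, since a second list of 14 striatal genes had a median of -0.25 with an SD of 0.25, lower in 13 of 14, beyond the bound of -0.2. The opioid peptide gene Penk stood at 36.95 and 22.06 TPM. Of the second list 14 of 15 genes were detected in both libraries, but this cannot show whether cortical or striatal cells expressed them. A change within cortical cells therefore stays open.

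The genes over 2-fold apart between the libraries differed between the quantifications. Of the 24 genes, 79.2% were within 2-fold in the second quantification, and without 6 genes under 0.01 TPM there it was 72.2% of 18. Reads shared between genes may account for many of them, since 58.3% had a count that was not whole, against 16.7% of 12811 other genes. Such a count does not show whether the genes that share reads are near-identical copies. These shares also do not separate shared reads from other differences of method. Of 58 genes over 2-fold apart in the second quantification, 53 were within 2-fold in the first. Estimated transcript length remained undecided for the 24 genes as a set. In CPM 8 of them (33.3%) were within 2-fold, so their TPM ratios did not come from counts alone. The other 16 were over 2-fold apart in CPM too.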

How the results depend on the processing

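The settings with protein-coding genes alone, with both quantifications required, and without the choroid plexus and striatal lists were chosen after seeing the data. The number of genes over 2-fold apart, 24, became 58 in the second quantification, 312 at a mean count of 10, 2856 with no minimum count, 12 with posterior means and 4 when both quantifications were required. Lower minimums and the joint requirement act by admitting more or fewer genes, and the cause of the other changes was not tested. It stayed between 16 and 19 under 4 scalings, a pseudocount of 1 and protein-coding genes alone. The Pearson r of 0.994 became 0.991 with a pseudocount of 0.1, 0.997 with no filter, 0.992 in the second quantification and 0.996 with posterior means. The coefficient of variation of 0.0531 became 0.0511 at a mean count of 100, and the share of genes with the same top transcript became 73.6% at 50 TPM or more; the cause was not tested. The astrocyte shift of 0.10 reversed to -0.0018 in the second quantification, and the cause was not tested. Detected protein-coding genes ranged from 10294 to 13982, and from 13272 to 13380 without either replicate. Detected list members ranged from 114 to 153, with 145 to 153 without either replicate. Since detection asks for both libraries, leaving out a replicate could only keep or raise these numbers. The lists outside the random lists numbered 7 to 10, and this result needs both libraries. Scaling by TMM, by size factors or by the spike-in total each gave 10, since these scalings can hardly change a percentile. In 7 pairs the later gene was higher under each of the 5 alternatives run. Only the second quantification and the posterior means could have changed this count. FPKM keeps the ratio of genes within a library, and each pair pointed the same way in both libraries. The top transcript agreed for 75.4% to 76.7% without either replicate. List medians moved by more than their SD in 50 of 104 cases and pair ratios in 13 of 40. These totals include the cases without either replicate, which cannot move by more than the SD of both libraries. In the remaining cases every list median moved except the choroid plexus and striatal ones in the second quantification. Without replicate 1 or without replicate 2 the choroid median was 2.02 or 0.50. At 1 TPM and 1 kb about 20 counts stand behind a value, which limits genes under that level.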

Other observations

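The 6 later lists were fixed after part of the data had been seen, and their genes named here were chosen after their values were seen. Neuropeptide and trophic factor genes had 15 of 15 members detected and a median of 12.5 ± 0.721 TPM (SD, n = 2). Cck stood at 170 ± 7.43, Vgf at 97.7 ± 1.91 and Chgb at 89.7 ± 2.59, while the neurotrophin gene Bdnf stood at 5.75 ± 0.431. Genes of the perineuronal and extracellular matrix had 11 of 12 detected and a median of 24.4 ± 1.61. Sparcl1 reached 496 ± 13.4 and the proteoglycan gene Ncan 185 ± 3.10, while Acan, the core of the nets around mature interneurons, stood at 1.525 ± 0.049. Voltage-gated sodium and potassium channel genes had 15 of 15 detected and a median of 35.6 ± 0.70, with Scn2a at 160 ± 5.72 and Scn8a at 77.9 ± 1.94.

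Between the libraries the neuropeptide list lay at percentile 49.1 of its random lists, the matrix list at 4.02 and the channel list at 1.76, the last outside their central 95%. The second choroid plexus list lay at 99.99, the motile cilia list at 63.9 and the second striatal list at 0, the first and last of these also outside. The second choroid plexus list had a median of 0.53 TPM in replicate 1 and 1.295 in replicate 2, the motile cilia list 0.56 and 0.66, and the second striatal list 14.98 and 13.0. The channel list had a median log2 ratio of -0.031, just beyond the lower limit of -0.028 of its random lists. Of its members 6 were up and 9 down, the lowest at -1.08. The cause of the channel list's position was not tested.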
